A study of Homo sapiens with 6 samples.

How the data were processed

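Total RNA from 6 LS180 samples was prepared with TRIsure, labelled with biotin and hybridised by the standard Affymetrix procedure, per the labels. The background correction, the normalization between arrays and the summarisation of probes are not given in the sources used here. The deposited table holds log2 expression values that the authors had centred within each pair of a knockdown array and the control array named for it. This was read from the values: the 2 values of a probe set sum to 0 within 1e-06 in every pair. The log base is not stated and was assumed to be 2.

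The centring limits what can be computed. A pair keeps 1 number per probe set, the difference of its arrays, which was taken as knockdown minus control. Expression levels and the spread between control arrays are gone. A test with limma had been planned on the spread between controls. It was not run, since each control column only mirrors its own pair. For the same reason the filter on low values, quantile normalization, other control arrays, arrays left out in turn and random lists matched on expression could not be had. Log values need no pseudocount. Each knockdown has 1 array, so no p-value is given for a gene or a list.

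The table has 44629 probe sets. The platform's annotation lists 15835 of them with 1 gene symbol and 0 with several, and 28794 are unlisted and unnamed here. All 15835 identifiers matched the gene table of assembly GRCh38.p14, which was used for names, gene types and lengths. They gave 14812 genes, 11911 of them protein-coding. The planned choice of the probe set with the highest mean needs levels, so the mean of a gene's probe sets, which had been listed beforehand as another choice, was used. Of the genes, 651 had several probe sets, and the median standard deviation between these was 0.10, 0.08 and 0.06 in the CTNNB1, MYC and MYU pairs. Between 3.03% and 3.84% of probe sets had a difference of exactly 0. Over all probe sets the standard deviation of the differences was 0.39, 0.23 and 0.17, and the column medians lay at 0 or within 0.00386 of it.

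Genes were counted at a 2-fold difference, with 1.5-fold as an alternative. The 23 gene lists, the samples' groups, the comparisons and the rule for named genes were fixed before the data were examined. List members not found among the 14812 genes were not measured and are not counted. Measured were 15 of 29 p53 targets, 27 of 50 replication genes, 38 of 62 MYC targets and 3 of 12 fibroblast markers. The rule takes the targeted transcripts, the 10 highest and 10 lowest genes per pair, up to 4 members per list with the largest absolute difference, and every measured cell cycle regulator and MYU neighbour. Its conditions on the sign against every control array and on limma calls could not be applied. Uncharacterised symbols were left out of the named genes. A list's median was set against 10000 random lists of protein-coding genes of the same size, as a description of these arrays. A second background, chosen after seeing the data, used 661 genes whose values carry the coarser rounding step of single precision. This step was taken to mark a level of at least 8, which could not be checked without levels. Whether the mark depends on the size of a difference was not tested. The step marked 12 of 43 ribosomal protein genes and 0 of 91 tissue-restricted genes (Fisher's exact test, two-sided, p = 3.64e-07). The tissue-restricted families were also chosen after seeing the data.

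Overlaps were compared with the product of the list sizes over the number of genes. Alternatives were centring each array on its median, the probe set nearest to 0 for each gene, the 1.5-fold threshold, all probe sets whether named or not, and the second background. In all, 9 tests of technical explanations were run. A first test of a shared control array, a test on tissue-restricted genes, a test without the MYC, replication and mitosis lists and a test of control arrays on genes lower in all 3 pairs had bounds that proved unable to exclude their explanations, and these verdicts were set to open after their values were seen. A further test of the shared control, a slope with 1000 bootstrap draws over genes, was then added.

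The calculations were tested on simulated data of 14812 genes for each of the CTNNB1, MYC and MYU pairs. In each, 100% of genes with a true log2 difference of 1.5 or 3 were recovered at 2-fold, 0% of those at 0.5, and 0 of 14612 unchanged genes were called. The noise was drawn at the standard deviation of the tissue-restricted genes (0.12, 0.09 and 0.10), so these outcomes were fixed by the setting. They check the code only. The differences of high-level genes had standard deviations of 0.88, 0.43 and 0.32, so the rate of false calls among well expressed genes is unknown. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.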

Results

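Gene expression was measured with Affymetrix arrays in LS180 cells, an established human colorectal adenocarcinoma line. The cells received an siRNA against CTNNB1, which encodes beta-catenin, the transcriptional effector of Wnt signalling, against the transcription factor MYC, or against the long non-coding RNA MYU, listed as VPS9D1-AS1. Each of the 3 knockdowns had 1 array, and each had 1 control siRNA array named for it, giving 6 arrays in 3 pairs. Values below are log2 differences, knockdown minus its own control, with log base 2 assumed from the values. With 1 array on either side no difference has a replicate check and no p-value is given, so "higher" and "lower" describe these arrays. The number of arrays limits the precision.

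As a yardstick of measurement noise, 91 genes of families little used outside their own tissues, such as olfactory and taste receptors, had a standard deviation of 0.12 in the CTNNB1 pair, 0.09 in the MYC pair and 0.10 in the MYU pair. None of the 91 reached a 2-fold difference in any pair. None of them carried the mark of a high level, so the noise of well expressed genes is not covered by this yardstick.

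The targeted transcripts were examined first. MYC was lower in the MYC siRNA array by 2.27-fold (-1.18), and it was lower still in the CTNNB1 siRNA array, by 5.21-fold (-2.38). In the MYU siRNA array MYC differed from its control by 0.04. VPS9D1-AS1 was 1.41-fold lower with MYU siRNA (-0.50), a value below which lay 1.96% of all genes. The same transcript had a value of -0.53 with CTNNB1 siRNA and -0.24 with MYC siRNA. CTNNB1 itself was not analysed here, because no probe set is listed with it, so that knockdown has no direct check. The treatment tag of that array names CTNNB2, while its title and source name give CTNNB1.

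The CTNNB1 pair asked which transcripts differ when beta-catenin is targeted. Some genes of differentiated intestinal epithelium were far higher in the knockdown array. CEACAM7, an adhesion molecule of mature colonocytes, was 59.6-fold higher (5.90). GUCA2A and GUCA2B, the precursors of guanylin and uroguanylin, were higher by 5.46 and 3.60, and the intermediate filament gene KRT20 by 4.39. Genes of DNA replication and mitosis were lower, among them the ubiquitin ligase adaptor gene DTL at -2.86 and PCNA, the sliding clamp of DNA polymerases, at -2.40. Of 14812 genes, 1028 were at least 2-fold apart, 415 higher and 613 lower.

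Of 22 enterocyte genes measured, 11 were at least 2-fold higher, 0 were lower and the other 11 lay within 2-fold, with a median of 0.95. The goblet and secretory list had 7 of 20 genes higher and 0 lower, with a median of 0.66. Its leading members were the trefoil peptide genes TFF2 (4.36), TFF1 (3.18) and TFF3 (1.89) and SPDEF (2.24), a transcription factor of secretory cells. Among all genes, FER1L6 (4.48), MUCL3 (3.94), EMP1 (3.61) and the protease inhibitor gene SLPI (3.49) also stood near the top. Of 20 epithelial and mesenchymal genes 2 were 2-fold higher, KRT19 (2.09) and the tight junction gene OCLN (1.14).

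Of 34 Wnt target genes, 8 were at least 2-fold lower and 3 higher, with a median of -0.40. The feedback regulator AXIN2 had a value of -2.23, the surface receptor CD44 -2.13, the stem cell receptor LGR5 -2.09 and CDCA7 -2.05. DKK1, a secreted Wnt antagonist, was higher at 1.69. The list lay below all random lists of protein-coding genes, but at percentile 11.6 of lists drawn from genes marked as high level. Those high-level genes were themselves shifted in this pair, with a median of -0.19 and 24.7% of them 2-fold apart, against 6.94% of all genes. Of 19 Wnt pathway components, FZD3 (-1.33) and FZD6 (-1.06), both receptor genes, were 2-fold lower and the plakoglobin gene JUP (1.38) was higher.

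DNA replication genes were lower in 27 of 27 cases, 24 of them at least 2-fold, with a median of -1.57. TYMS, the thymidylate synthase gene, had a value of -2.29 and MCM10 -2.23. Mitosis genes were lower in 34 of 34 cases, 29 at least 2-fold, with a median of -1.62. They included the cyclin gene CCNA2 (-2.28), the kinesin gene KIF11 (-2.17), TOP2A (-2.17) and the kinase gene AURKB (-2.10). Outside these lists, TICRR (-2.57), the exonuclease gene EXO1 (-2.42) and MCM8 (-2.31) were among the lowest, with the RNA polymerase III subunit gene POLR3G (-2.59), the receptor gene IL17RB (-2.43), GEMIN5 (-2.37) and EXOSC2 (-2.34).

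MYC target genes were lower by at least 2-fold in 25 of 38 cases and higher in 0, with a median of -1.29. NOLC1, a nucleolar protein gene, had a value of -2.21. Ribosomal protein genes were below 0 in 31 of 31 cases with a median of -0.60, 3 of them 2-fold lower, including RPS23 (-1.24). Of 11 genes listed as repressed by MYC, 4 were 2-fold higher, among them MXD1, an antagonist of MYC, at 3.52 and KLF6 at 2.23, with a list median of 0.85, or 0.36 when the probe set nearest to 0 stood for each gene. Cholesterol and lipid synthesis genes had a median of 0.49 and 6 of 22 were 2-fold higher, including INSIG1 (1.25), a regulator of sterol synthesis, and SQLE (1.09), the squalene epoxidase gene. Of 30 interferon response genes 5 were 2-fold higher, led by SAMD9 (2.87) and SAMD9L (1.92), with a median of 0.16. Medians were 0.21 for stress genes, 0.22 for the MYC network, 0.06 for NF-kappaB genes, -0.13 for glycolysis with LDHB at -1.35, and -0.14 for RNA interference genes with XPO5 at -1.41.

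Markers of other cells were checked in the same pair. Of 3 fibroblast markers LUM was higher at 2.78 while DCN had a value of 0.01 and THY1 -0.04, and 0 of 6 leukocyte markers were 2-fold apart. Of 7 housekeeping genes PPIA (-1.20) and HPRT1 (-1.19) were 2-fold lower. Of the 23 lists, 8 lay above and 6 below the central 95% of 10000 random lists of protein-coding genes. The random lists were not matched on expression level, and a difference at this size comes from a single pair of arrays.

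**Figure D1:**
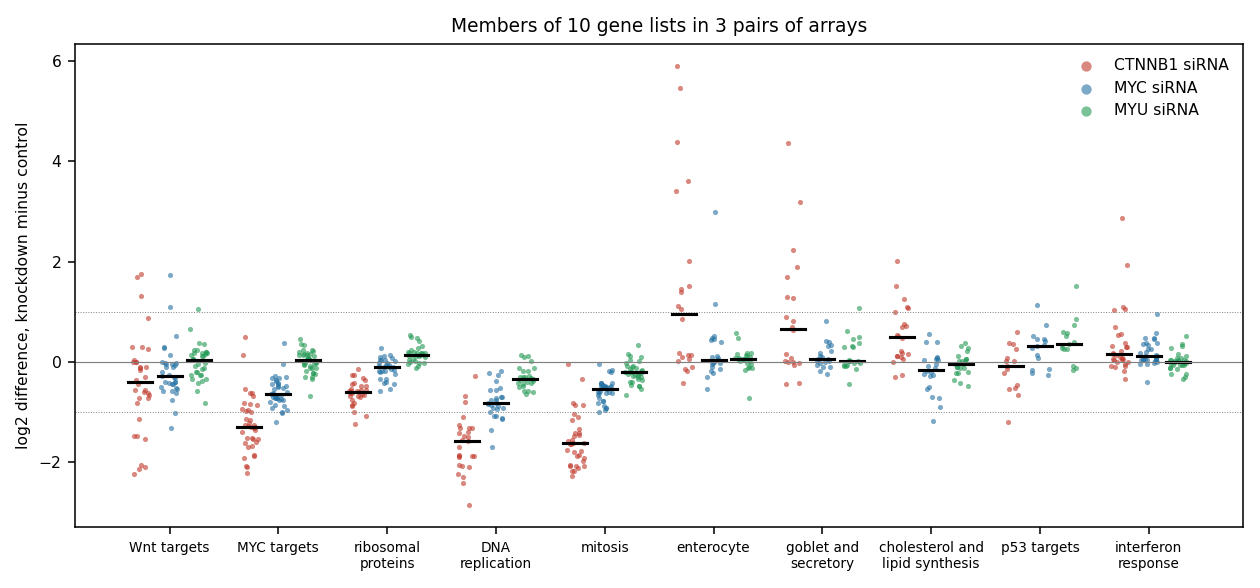
Members of 10 gene lists, 1 point per gene, with the log2 difference of knockdown minus control on the vertical axis for the CTNNB1, MYC and MYU siRNA pairs; black bars are list medians and dotted lines mark a 2-fold difference. DNA replication medians lie at -1.57, -0.82 and -0.34 in the 3 pairs, and the enterocyte medians at 0.95, 0.04 and 0.07.

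The MYC pair asked the same of MYC. Fewer genes were 2-fold apart, 127 in all, with 61 higher and 66 lower. Over all probe sets, named or not, the balance turned, with 151 higher and 118 lower, while 319 genes were higher and 538 lower at 1.5-fold. CEACAM7 again had the highest value, 7.97-fold, followed by SLPI (1.98), the ubiquitin ligase gene TRIM31 (1.81) and DKK1 (1.74). TM4SF4 (1.68), the matrix glycoprotein gene THBS1 (1.66), ERP27 (1.66), the sialidase gene NEU1 (1.53), CDHR5 (1.45) and ENPP5 (1.42) completed the highest 10. The lowest were the cytochrome gene CYB5A (-1.95), MCM10 (-1.68), the neuropeptide gene GAL (-1.57), GTF3A (-1.55), a factor for 5S ribosomal RNA transcription, STYX (-1.54) and the lamin B receptor gene LBR (-1.51). POLR3G (-1.48), ZNF367 (-1.46), KLK7 (-1.46) and NFIC (-1.44) came next.

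Of 38 MYC target genes, 22 were at least 1.5-fold lower and 2 at least 2-fold lower, with a median of -0.63. The latter were TCOF1 (-1.19), needed for ribosomal RNA transcription, and the nucleolar methyltransferase gene NOP2 (-1.01). Ribosomal protein genes had a median of -0.10, and 0 of 31 were 1.5-fold apart. DNA replication genes were lower in 27 of 27 cases, 6 of them 2-fold, with a median of -0.82. DTL had a value of -1.35, UHRF1 -1.14 and the replication licensing gene CDC6 -1.11. Mitosis genes had a median of -0.53, with 34 of 34 below 0 and 15 at least 1.5-fold lower, among them CCNA2 (-0.99). Of 11 genes listed as repressed by MYC 7 were below 0 in this pair, with a median of -0.07 and MXD1 at -0.51, and THBS1 was 2-fold higher.

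The enterocyte median was 0.04, with only CEACAM7 and KRT20 (1.16) of its 22 genes 2-fold higher, and 0 of 20 goblet and secretory genes were 2-fold apart. Wnt targets had a median of -0.29, with AXIN2 at -0.27 and LGR5 at 0.30. Of 34 members, CDCA7 (-1.32) and CEMIP (-1.01) were 2-fold lower, and CLDN1 (1.09) and DKK1 (1.74) were 2-fold higher. The Wnt target list lay at percentile 1.52 of lists of high-level genes, below their central range. Of 15 p53 target genes TP53I3 was 2-fold higher (1.14) and the median was 0.32. Of 18 stress genes DDIT4 was 2-fold lower (-1.42), of 22 lipid synthesis genes ELOVL6 (-1.18), and of 12 NF-kappaB genes the chemokine gene CCL20 (-1.02). In the list of interferon genes the median was 0.12. Glycolysis genes had a median of -0.29, with HK2 at -0.76 and LDHA at -0.71. The stress, glycolysis, lipid synthesis and ribosomal protein lists lay within the central range of lists drawn from genes marked as high level.

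The MYU pair asked which transcripts differ when this RNA is targeted. GDF15, a stress-induced growth factor gene, was higher by 1.52, or 2.86-fold. Also higher were SCARNA9 (1.10) and SCARNA2 (1.03), which guide RNA modification, and the transcription factor genes NEUROG3 (1.08) and PROX1 (1.06). ARL6IP5 (1.07), the metallothionein gene MT1G (1.03), the argininosuccinate synthase gene ASS1 (1.02) and SNHG16 (0.95) followed. MIR3189 (1.46) lies within GDF15 and is not an independent value. Of all genes 23 were 2-fold apart, 9 higher and 14 lower, against 24 higher and 24 lower over all probe sets.

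The lowest gene was GPR15LG (-1.65), followed by the kinesin gene KIF20B (-1.37), CRYBG1 (-1.19), ANTXR2 (-1.18), the deubiquitinase gene USP25 (-1.17) and CDK6 (-1.17), a kinase of the G1 phase. MAP3K20 (-1.15), MIR4653 (-1.15), MBOAT1 (-1.11) and RHOBTB3 (-1.10) came next. DNA replication genes had a median of -0.34, with 23 of 27 below 0, 3 at least 1.5-fold lower and 0 at 2-fold. These were GINS2 (-0.64), MCM10 (-0.61) and GINS3 (-0.59). Mitosis genes had a median of -0.21, with 28 of 34 below 0 and NUSAP1 (-0.66) at 1.5-fold. Of 15 p53 targets 12 were above 0, with a median of 0.36, led after GDF15 by SESN1 (0.85) and TRIAP1 (0.74). CDKN1A and MDM2 are not among the 15, so the median covers only part of the p53 targets. In the CTNNB1 pair 8 of these 15 were below 0, with a median of -0.08 and TRIAP1 at -1.19. Ribosomal protein genes were above 0 in 26 of 31 cases, with a median of 0.14, while MYC targets had a median of 0.03 and Wnt targets 0.05.

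In this pair, values went with gene length. Spearman's rho between length and difference across 11911 protein-coding genes was -0.17, against -0.01 in the CTNNB1 pair and 0.02 in the MYC pair. Among the 2978 longest genes 61 were 1.5-fold lower and 8 higher, and among the 2978 shortest 9 were lower and 32 higher. After the trend was taken out, CDK6 had a value of -1.15 and the replication list a median of -0.33. Other values of this pair, such as those of the ribosomal protein genes, were not corrected for the trend. Genes are not independent replicates.

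Regulators of the G1 to S transition were examined singly in all 3 pairs. CDK6 had values of -1.12, -0.91 and -1.17 with CTNNB1, MYC and MYU siRNA. CDK4 had values of -1.88, -0.63 and 0.24, and E2F1, an activator of S-phase genes, of -1.39, -0.75 and 0.12. The pocket protein gene RBL1 was at -1.24 with MYC and -0.84 with MYU siRNA and lower still with CTNNB1 siRNA, and RB1 was at -0.42, 0.08 and -0.80. HNRNPK, an RNA-binding protein gene, had values of -0.50, -0.11 and -0.13. CCND2 stood at 0.64 with MYU siRNA, where its probe sets disagreed (0.13 and 1.15). In the CTNNB1 and MYU pairs the list of 16 regulators lay within the central range of lists of high-level genes.

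**Figure D2:**
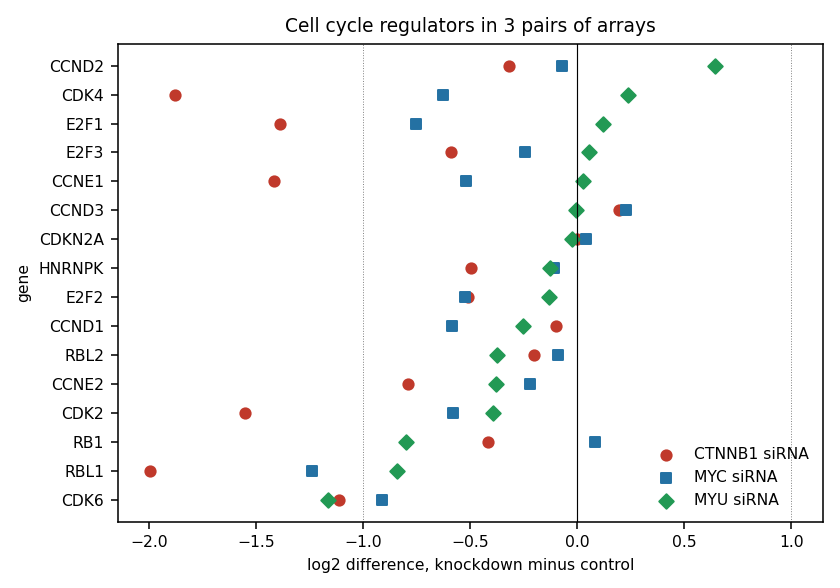
Log2 difference of knockdown minus control (horizontal axis) for each of 16 cell cycle regulator genes (vertical axis) in the CTNNB1, MYC and MYU siRNA pairs, with dotted lines at a 2-fold difference. CDK6 lies at -1.12, -0.91 and -1.17, and CDK4 at -1.88, -0.63 and 0.24.

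Genes next to MYU were also followed. VPS9D1, the neighbour on which the RNA's symbol is based, differed by 0.08 with MYU siRNA. Of 10 neighbours 0 were 1.5-fold apart in that pair, with CDK10 at -0.44 and CPNE7 at -0.43. In the CTNNB1 pair SPIRE2 was higher at 1.07, and CPNE7 had values of -0.70 and -0.73 in the CTNNB1 and MYC pairs.

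The last comparison asked how far the knockdowns move the same genes. Of the 66 genes 2-fold lower with MYC siRNA, 41 were also 2-fold lower with CTNNB1 siRNA, among them MCM10 and POLR3G, against 2.73 for unrelated lists. Of the 61 higher genes 35 were shared, among them CEACAM7 and SLPI, against 1.71. Between CTNNB1 and MYU siRNA 3 lower genes and 1 higher gene were shared, against 0.579 and 0.252. At 1.5-fold these knockdowns shared 67 lower and 22 higher genes, against 17.5 and 6.38. MYC and MYU siRNA shared 0 genes at 2-fold in either direction, and 45 lower and 19 higher genes at 1.5-fold, against 6.50 and 2.13. Of the 127 genes 2-fold apart with MYC siRNA, 120 (94.5%) had the same sign with CTNNB1 siRNA. Of the 23 genes 2-fold apart with MYU siRNA, 9 (39.1%) had the same sign with CTNNB1 siRNA and 12 (52.2%) with MYC siRNA. The numbers for unrelated lists leave out any control shared between pairs, which could also raise the shares of genes with the same sign. They also treat all genes alike. With CTNNB1 siRNA 24.7% of genes marked as high level were 2-fold apart, against 6.94% of all genes, so these numbers may be too low.

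Across 14812 genes Pearson's r was 0.61 between the CTNNB1 and MYC pairs (Spearman's rho 0.51), 0.11 between CTNNB1 and MYU (rho 0.06) and 0.15 between MYC and MYU (rho 0.10). The control titles of the CTNNB1 and MYC pairs carry the same number, and whether they are one hybridisation is not known. The control title of the MYU pair carries another number, so the simulation below matches at most the CTNNB1 and MYC pairs. Unchanged groups simulated against one shared control, with the noise of the tissue-restricted genes, gave r of 0.50, a covariance of 0.00552 and 0 shared genes at 2-fold in either direction. This r and the 0 shared genes follow from the setting and decide nothing about these arrays. Across the tissue-restricted genes themselves r was 0.38, 0.17 and 0.19 in the same order of pairs. The noise of those genes does not cover well expressed genes. The observed covariances were 0.0852, 0.0109 and 0.00831. Part of the excess may come from shared controls, which the values do not allow to be split.

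Lists were compared between knockdowns as medians of the genewise differences. Mitosis genes were lower with CTNNB1 than with MYC siRNA by a median of -1.03, replication genes by -0.87 and MYC targets by -0.61. Enterocyte genes were higher by 0.66 and lipid synthesis genes by 0.60. For Wnt targets the difference was only -0.11, against a lower random bound of -0.10. MYC itself was also lower with CTNNB1 than with MYC siRNA. Differences in the CTNNB1 pair were wider over all probe sets, with a standard deviation of 0.39 against 0.23. These gaps therefore cannot be read as particular to beta-catenin. MYC targets were lower with MYC than with MYU siRNA by -0.63 and replication genes by -0.59. For p53 targets that difference was -0.12, within the central range of random lists, while CTNNB1 against MYC siRNA gave -0.37 and CTNNB1 against MYU siRNA -0.44, both below that range. Single genes were not tested for a difference between knockdowns.

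**Figure D3:**
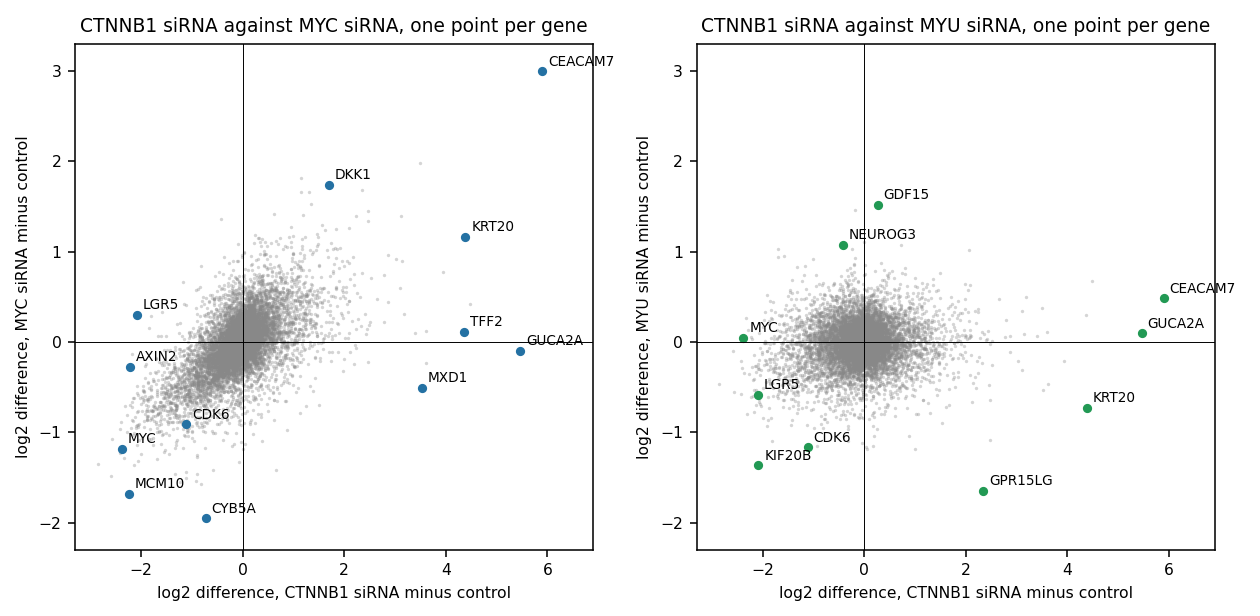
Log2 difference with CTNNB1 siRNA (horizontal axis) against that with MYC siRNA (left) and MYU siRNA (right), knockdown minus control on every axis, 1 point per gene with some genes named. Pearson's r across genes is 0.61 on the left and 0.11 on the right.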

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

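The slope test, the tissue-restricted test and the tests on genes lower in all 3 pairs were chosen after the results were seen.

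Probe sets with no listed gene also differed. With CTNNB1 siRNA 677 of 28794 such probe sets were 2-fold apart, with MYC siRNA 131 and with MYU siRNA 21. They stand outside the gene comparisons, and whether these differences exceed noise was not tested.

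The CTNNB1 and MYC differences correlated across genes. If a shared control array were the only link, the slope of the CTNNB1 on the MYC difference could not pass 1. The slope was 1.11 (95% bootstrap interval over genes 1.07 to 1.15). This argues against a shared control as the whole cause only if both pairs have the same scale, which cannot be checked without levels. The interval resamples genes, which are not independent, and leaves out variation between arrays. An earlier test, the median ratio of the MYC to the CTNNB1 difference of 0.361, met the bound set for it, but that bound was wrong because CTNNB1's own differences lower the ratio, so it decides nothing. The covariance was 19.4 times that of the tissue-restricted genes, which also decides nothing, since 0 of those 91 genes carry the mark of a high level. Without the 96 genes of the MYC, replication and mitosis lists r was 0.592, which decides nothing either, since r was 0.565 without the 96 genes that add most to the covariance. A shared control as part of the relation stays open, and a response common to both knockdowns, with MYC itself lower in both, is a candidate explanation.

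DNA replication genes were lower in the MYU pair. A trend with gene length as the whole cause is argued against by a median of -0.33 after the trend was removed, below the random range of -0.06 to 0.06. Of random lists of high-level genes 0% had a lower median, so the list lay below high-level genes drawn singly. This decides nothing about a wide spread of well measured genes, since genes of a list may vary together between arrays. In this pair 9 of 23 lists lay outside the central range of random lists of protein-coding genes. A spread between the arrays of the pair therefore stays open. Differences in growth between the 2 cultures of the pair stay open, as does an effect of the siRNA other than on MYU, and no second siRNA was analysed here.

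There were 35 genes at least 1.5-fold lower in all 3 pairs, of which 5 (CDK6, GINS2, GINS3, MCM10 and RBL1) belong to the replication, mitosis or regulator lists. The 35 also hold CDC7, KIF14, MCM8 and TRIP13, which these short lists leave out. The 5 are therefore not a count of all genes of replication and mitosis among them. Differences in growth between the cultures of a pair were not tested. The 35 genes are 54.9 times the number for unrelated lists. That number leaves out any shared control, the relation between the CTNNB1 and MYC pairs and expression level, so it may be too low. The CTNNB1 value lay below the MYU value by a median of -0.93 (interquartile range -1.24 to -0.56). This decides nothing about an effect of the control arrays, since differences in the CTNNB1 pair are wider and the control of the MYU pair has another number, so that explanation stays open. For CDK6 the 3 values span 0.256, so an effect of the controls and one of the knockdowns cannot be told apart, because levels in the controls are gone.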

How the results depend on the processing

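The nearest-to-0 probe set, the 1.5-fold threshold, all probe sets and the high-level background were chosen after seeing the data. At 1.5-fold, 2406, 857 and 278 genes were apart in the CTNNB1, MYC and MYU pairs, by the looser threshold's construction. Over all probe sets, named or not, 1756, 269 and 48 were 2-fold apart, since more features are counted. Taking the probe set nearest to 0 left the 3 counts and all 12 overlaps within 1.5 times. Of 69 list values this choice kept 66 on their side of the random range and moved 2 outside and 1 inside it. Only 651 of 14812 genes have several probe sets, so most values could not change and this says little about stability. The list differences between knockdowns were not recomputed with that choice. Centring each array on its median over genes, already 0, moved no value and so says nothing about stability. Against high-level genes 56 kept their side and 13 moved inside the range. Of these genes 24.7%, 2.72% and 0.454% were 2-fold apart in the CTNNB1, MYC and MYU pairs, against 6.94%, 0.857% and 0.155% of all genes. The cause of the moves was not tested. Limma, the filter on low values, quantile normalization, other or averaged controls, pseudocounts and arrays left out in turn were not run, because levels and the spread between controls are gone. No test within a pair was possible, since each has 1 array on either side. Signal over background is unknown, so small differences of low genes cannot be told from noise.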

Other observations

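The gene families here are among 14 chosen after the results were seen, and their values are descriptions. In the MYU pair they were not corrected for the trend with gene length, in which shorter protein-coding genes ran higher. Small Cajal body RNAs, which guide modification of spliceosomal RNAs, were above 0 in 20 of 21 cases with MYU siRNA, with a median of 0.47, against -0.01 with CTNNB1 siRNA and 0.16 with MYC siRNA. SCARNA17 had a value of 0.79 and SCARNA6 of 0.76. Of 9 metallothioneins, which bind zinc and copper, 8 were above 0 with MYU siRNA and 1 was 2-fold higher, with a median of 0.37. With CTNNB1 siRNA 7 were below 0 and 4 were 2-fold lower, with a median of -0.57, and MT1X stood at -1.92 and MT1G at -1.70. The median with MYC siRNA was -0.13, and differences between the knockdowns were not tested. TERC, the RNA component of telomerase, had values of -0.59, -1.01 and 0.64 with CTNNB1, MYC and MYU siRNA.

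Some of the other families had medians well below 0 with both CTNNB1 and MYC siRNA, and the difference between these knockdowns was not tested. Medians of others lay near or above 0, such as kinesins (-0.02 and -0.01), zinc finger genes (-0.05 and 0.03) and tetraspanins (0.10 and 0.14). Nucleoporins had medians of -0.92 and -0.43, with NUP107 at -1.71 and -0.90. Mitochondrial ribosomal proteins had medians of -0.54 and -0.18 over 77 genes, with MRPL3 at -1.26 and -0.08. Subunits of RNA polymerases I and III stood at -0.75 and -0.38, and aminoacyl tRNA synthetases at -0.32 and -0.24. In the opposite direction, 10 genes were at least 1.5-fold higher in all 3 pairs, against 0.137 for unrelated lists. That number leaves out any control shared between pairs, the relation between the CTNNB1 and MYC pairs and expression level, so it may be too low. The 10 genes included the lysosomal genes GRN (1.36, 0.98 and 0.70) and NEU1 (1.36, 1.53 and 0.63), the ceramidase gene ACER2 (2.09, 1.26 and 0.63) and VAMP8 (1.49, 1.08 and 0.77), a gene of vesicle fusion.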
